A study of Homo sapiens with 21 samples.

How the data were processed

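RNA sequencing libraries were made from total RNA with the Nextera XT kit and sequenced paired-end on an Illumina NextSeq instrument, per the labels' protocols. Reads were handled with bcl2fastq 2.17, STAR, RSEM 1.2.28 and DESeq2 against the builds GRCh38 and GRCm38, per the submitters' processing notes, which give no role or order for these tools. Human reads were separated computationally from mouse reads before the values were made, per the series' design text. The authors deposited one table of normalized values per gene and library, and the range, with values below 0 and near-constant values for genes with almost no reads, shows a log2 scale. How the authors normalized these deposited log2 values, which annotation release was used and whether strand was considered are not given in the sources used here. Values were close to a floor of -2.33 for nearly empty genes, so that differences of genes near the floor understate the change. No counts were used, so the depth of each library is unknown and no count model was applied; precision comes from the replicate spread alone.

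The table held 36959 genes in 21 libraries, and each of its columns matched the label of 1 library, with 0 columns left over. Of these genes, 6438 were listed at 0 in all libraries. Genes were tested if they had a value of at least 1 in at least 3 of the 21 libraries, which left 14704. No 2 libraries held identical values. Among tested genes, 23 in 7 sets had the same values as another gene in all libraries, and near-identical copies were not named as results. Libraries were grouped by culture and treatment as the labels give them, with 3 per group. The design had assumed linear values with a pseudocount; because the values were on a log2 scale already, they were used as deposited, as the design had foreseen, with no pseudocount.

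A means model of the 7 groups was fitted to all 21 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trended prior variance, two-sided), without a replicate block. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Comparisons were each co-culture against monoculture, untreated and under the same steroid; the untreated co-cultures against each other; each steroid against untreated within each culture; and the difference of each steroid's effect between co-culture and monoculture. These comparisons, their alternatives, the gene lists and the rule for named genes were set before the data were examined. The direct comparison of E2 with R1881 in monoculture was added afterwards.

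Gene lists numbered 32, with 533 entries, all found in the table. For each list the tested members called higher and lower were counted over all genes and adjusted over the list alone, and limma's camera tested whether the list moved relative to the other genes, with a preset correlation of 0.01 between genes, lists of at least 5 tested members and Benjamini-Hochberg adjustment over lists. An estimated correlation was the alternative, and its p is printed beside calls that it ended and beside some that it left standing. In untreated 4T1 co-culture the camera calls for osteoblast, osteoclast-regulating, structural matrix, TGF-β, NOTCH, NF-κB, interferon, cell cycle, estrogen-responsive and contractile lists also held with it, and in untreated TRAMP co-culture those for the structural matrix, NF-κB, osteoclast-regulating, osteoblast, protease, TGF-β, YAP, NOTCH and NRF2 lists. Some genes are in more than 1 list, such as IL6, COL1A1, TNFRSF11B, TAGLN (TGF-β and contractile), CTGF (TGF-β and YAP) and CXCL12 (osteoclast-regulating and estrogen-responsive). Markers of carcinoma, fat, cartilage, contractile, endothelial and blood cells served to look for other cell types.

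Genes named in the text were the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap, the 4 members with the smallest p from each list with a call, and a fixed set of hormone and osteoblast genes; with fewer than 5 calls, the called genes and the 5 with the smallest p. Fewer are printed than the rule takes, and a gene named outside it is marked as such where it appears. Results for some genes the rule takes are not reported here. Positions are from GENCODE 29 on GRCh38, 1-based, where 14651 of the tested genes had 1 position. GC content and transcript length from the same annotation were known for 14695 tested genes (99.9%).

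Alternatives were a looser filter (any log2 value above 0), a stricter filter at a linear value of 50, median centring, quantile normalization and array weights. Further ones were a constant prior variance, a fold change of at least 2, a replicate block, a fit of the compared libraries alone and leaving out each library in turn. Added after seeing the data were a correction for GC content and transcript length, protein-coding genes only, and leaving out the 2 libraries with raised low-abundance genes. The correction fitted splines to each library's deviation from the gene mean. These splines varied with mean abundance, so shifts that follow abundance were removed as well. Agreement between co-cultures was set against 100 simulations of unchanged groups sharing the same controls.

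The fit was tested on simulated data with known changes in the comparison of untreated 4T1 co-culture with monoculture over 14704 genes. It recovered 6% of 50 genes changed by 0.25 on the log2 scale, 74% of 50 at 0.5, 100% of 50 at 1 and 100% of 50 at 2, with 5 false calls. Comparisons simulated with no change gave 0 calls for TRAMP co-culture against monoculture, 0 for E2 and 1 for R1881 in monoculture, and 0 for R1881 in TRAMP co-culture. Of 100 random lists, 3 had a camera p under 0.05. Changed genes and lists were drawn from the more abundant genes only, so recovery of genes as low as ESR1 or PGR was not tested. Simulated values were independent between genes, so false calls from trends shared across a library, such as those with GC content, were not covered. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. The mouse transcripts of the co-cultured cancer cells were not analysed here.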

Results

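Gene expression was measured by RNA sequencing in FOB 1.19 cells, an established human fetal osteoblast line, kept in 3D culture without serum. The cells were grown alone (monoculture) or together with mouse cancer cells (co-culture), either 4T1 breast cancer cells or TRAMP prostate cancer cells, and the human transcripts are described here. Monocultures were untreated, or received 10 nM of the estrogen 17β-estradiol (E2) or 10 nM of the synthetic androgen R1881 for 24 h. Co-cultures with 4T1 cells were untreated or received E2, and co-cultures with TRAMP cells were untreated or received R1881, each at 10 nM for 24 h. Dose and time are those of the labels' treatment protocol, which speaks of mammospheres and does not mention the osteoblasts. This gave 7 groups of 3 libraries, 21 in all. The series asks how the bone microenvironment affects hormone-dependent breast cancer cells, and these libraries describe the bone-forming partner in the presence of cancer cells and steroids.

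Of 36959 listed genes, 14704 passed the filter on low values and were tested. Values were normalized log2 expression, so the depth of each library is unknown, and precision was taken from the spread between libraries. The median standard error of a difference between groups was 0.106 on the log2 scale, with a median 95% half-width of 0.216. Correlations across genes between libraries of a group lay between 0.9942 and 0.9978, where genes are not independent replicates. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Library medians lay between 5.40 and 5.46, and mitochondrial ribosomal RNA took 9.44% to 15.9% of the summed linear values. Genes of low abundance were raised in replicate 2 of the untreated monoculture, by 0.20 on the log2 scale on average, and in replicate 3 of the E2-treated 4T1 co-culture, by 0.13. Changes below are log2 differences ± SE from limma with Benjamini-Hochberg adjusted p, n = 3 libraries per group. For each gene named as changed between 2 groups, the 3 libraries of one group lay entirely above the 3 of the other.

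Untreated osteoblasts in monoculture held little transcript of the estrogen and progesterone receptors. The estrogen receptor gene ESR1 (chromosome 6, 151656691 to 152129619 on the plus strand of GRCh38) stood at 2.32 ± 0.34 (SD, n = 3), and ESR2 at 3.75 ± 0.25. The progesterone receptor gene PGR stood at 1.05 ± 0.25. For scale, the osteoblast transcription factor gene RUNX2 stood at 6.71 ± 0.08, the alkaline phosphatase gene ALPL at 2.97 ± 0.08 and the osteopontin gene SPP1 at 3.43 ± 0.07. FKBP5, a glucocorticoid-responsive gene, was at 5.91 ± 0.04.

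Libraries of osteoblasts grown with 4T1 cells held more matrix transcript and less inflammatory transcript than those of osteoblasts grown alone. Levels of these genes in the mouse cells themselves were not analysed here. Periostin (POSTN), a matrix protein of bone-lining tissue encoded on the minus strand of chromosome 13 (37562583 to 37598844, GRCh38), rose 10.7-fold, from 7.70 ± 0.14 to 11.11 ± 0.08 (SD, n = 3). The change was 3.42 ± 0.08 with adjusted p = 6.78e-25. The type I collagen gene COL1A1 (chromosome 17, 50183289 to 50201632, minus strand) rose 6.06-fold, from 9.60 ± 0.08 to 12.20 ± 0.13. The neutrophil chemokine CXCL8 (chromosome 4, 73740506 to 73743716, plus strand) was 14.1-fold lower, at 9.63 ± 0.04 against 13.45 ± 0.08, with adjusted p = 4.62e-27. Interleukin-6 (IL6; chromosome 7, 22725884 to 22732002, plus strand) was 9.74-fold lower, at 7.70 ± 0.17 against 10.98 ± 0.19. In all, 1587 genes rose and 1664 fell, of which 125 and 131 by at least 2-fold. The 3 libraries of each group did not overlap for 5014 genes (34.1% of those tested), where chance gives 10%.

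**Figure D1:**
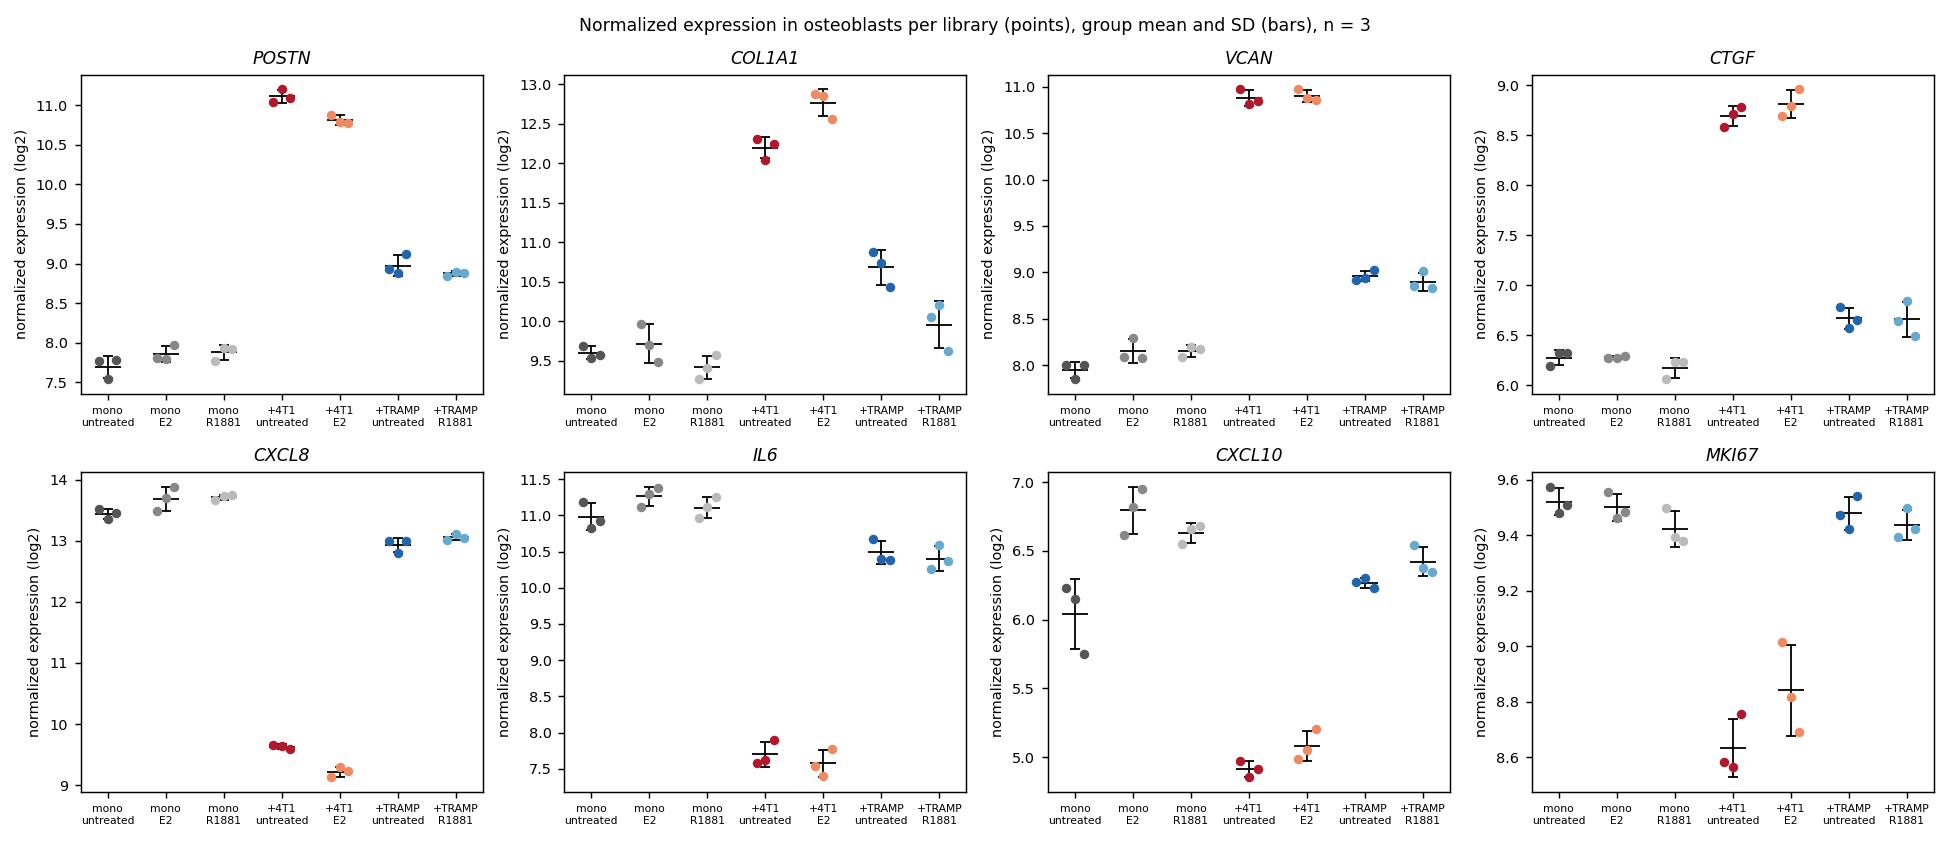
Normalized expression (log2, y axis) of 8 genes in each of the 21 libraries, grouped by culture and treatment on the x axis; points are libraries, and bars are the group mean and SD (n = 3). POSTN means rise from 7.70 in untreated monoculture to 8.97 with TRAMP and 11.11 with 4T1 cells, while CXCL8 means fall from 13.45 to 12.93 and 9.63.

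Structural matrix genes mostly rose. Of 23 tested, 17 rose and 5 fell, also adjusted over the list alone. The set as a whole was higher (median 0.83, camera adjusted p = 3.64e-13, and adjusted p = 0.014 with an estimated correlation). The fibrillar collagen gene COL5A3, outside this list, had the largest increase of all, 18.5-fold (4.21 ± 0.14, from 4.45 ± 0.26 to 8.66 ± 0.10; chromosome 19, 9959561 to 10010471, minus strand). The proteoglycan versican (VCAN) rose by 2.93 ± 0.08 and the collagen VI chain COL6A3 by 1.77 ± 0.08, whereas the matrix glycoprotein tenascin C (TNC) fell by 2.16 ± 0.09. Among 9 genes of contractile myofibroblasts, 5 rose and 0 fell, also adjusted over the list alone (median 0.64, adjusted p = 1.32e-07). These included the actin-binding genes TAGLN, 2.27 ± 0.11, CALD1, 1.71 ± 0.08, and TPM1, 1.37 ± 0.08. Targets of TGF-β rose in 8 of 14 cases and fell in 1 (9 and 1 adjusted over the list alone; median 0.60, adjusted p = 3.89e-09). They included the matricellular growth factor CTGF (2.42 ± 0.10, chromosome 6, 131948176 to 131951373, minus strand) and TGFBI (2.16 ± 0.07). TAGLN is in this list as well as in the contractile one. Of 5 NOTCH targets 4 rose, and 5 adjusted over the list alone (median 0.46, adjusted p = 4.09e-06). Among them were NOTCH3, 1.75 ± 0.12, and HEY1, 0.46 ± 0.11.

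Targets of NF-κB, the transcription factor of acute inflammation, fell almost as a whole. Of 23 tested, 22 fell and 0 rose, also adjusted over the list alone. The set was lower (median -2.13, adjusted p = 1.65e-52, and 3.72e-05 with an estimated correlation). They included the prostaglandin synthase PTGS2 (-3.74 ± 0.09; chromosome 1, 186671791 to 186680427, minus strand), the chemokine CXCL1 (-3.66 ± 0.11; chromosome 4, 73869393 to 73871242, plus strand) and the granulocyte growth factor CSF3 (-3.38 ± 0.11). The protease inhibitor TFPI2, outside the list, fell by 3.54 ± 0.08. Factors that regulate osteoclasts, the bone-resorbing cells, overlapped with this list. They fell in 9 of 11 cases with 0 rising, also adjusted over the list alone (median -1.78, adjusted p = 9.36e-18). Besides IL6, they held interleukin-11 (IL11, -2.38 ± 0.11), CXCL12 (-1.34 ± 0.11) and TNFRSF11B, which encodes the osteoclast inhibitor osteoprotegerin (-2.04 ± 0.09, 4.13-fold lower; chromosome 8, 118923557 to 118952200, minus strand). Interferon-stimulated genes fell in 19 of 23 cases and 20 adjusted over the list alone, with 0 rising (median -0.70, adjusted p = 4.68e-18, and 0.014 with an estimated correlation). Among these, the antiviral genes IFI44L and OAS3 fell by 1.15 ± 0.09 and 0.94 ± 0.08, and the chemokine CXCL10 by 1.13 ± 0.11.

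Genes of the cell division cycle fell in 17 of 25 cases and 18 adjusted over the list alone, with 0 rising (median -0.34, adjusted p = 1.08e-08, and 0.0148 with an estimated correlation). The proliferation marker MKI67 fell by 0.89 ± 0.08, from 9.52 to 8.63, the nucleotide synthesis gene RRM2 by 0.86 ± 0.08 and the replication helicase gene MCM3 by 0.84 ± 0.08. Osteoblast markers went both ways. Of 13 tested, 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.02, a mean of 0.52 and adjusted p = 9.48e-05. SPARC, encoding osteonectin, rose by 2.31 ± 0.07, the osteoblast cadherin CDH11 by 1.57 ± 0.08, SPP1 by 0.60 ± 0.12 and RUNX2 by 0.55 ± 0.09. ALPL differed by -0.04 (95% interval -0.28 to 0.21) and did not pass.

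Secreted and surface factors were mixed. Matrix proteases and their inhibitors rose in 7 and fell in 6 of 19 cases (7 and 7 adjusted over the list alone; median -0.08, adjusted p = 0.954). The collagenase MMP1 had the change -1.40 ± 0.09, stromelysin MMP3 -1.60 ± 0.12 and ADAM12 1.28 ± 0.09. Growth factors rose in 5 and fell in 10 of 19 cases, also adjusted over the list alone (median -0.32, adjusted p = 0.0977). Among the falls were FGF2, -1.89 ± 0.09, and the angiogenic factor VEGFA, -0.79 ± 0.08. Adhesion and junction genes rose in 4 and fell in 5 of 18 cases (4 and 6 adjusted over the list alone; median -0.05, adjusted p = 0.954). Examples were the integrin ITGAV, 1.09 ± 0.08, and the gap junction gene GJA1, -0.71 ± 0.07. Targets of BMP rose in 2 of 14 cases, also adjusted over the list alone (median -0.05, adjusted p = 0.954), one being ID3 at 0.59 ± 0.11. YAP targets rose in 2 of 10 cases, also adjusted over the list alone (adjusted p = 0.0086, but adjusted p = 0.0659 with an estimated correlation). They were CTGF and CYR61, 0.72 ± 0.12. Targets and inhibitors of WNT signalling rose in 1 and fell in 1 of 11 cases (1 and 2 adjusted over the list alone; median 0.02, mean -0.15, adjusted p = 0.621). The fall was that of the WNT antagonist SFRP1, -1.79 ± 0.08.

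Stress and metabolic groups were tested too. Hypoxia and glycolysis genes rose in 1 and fell in 9 of 21 cases, also adjusted over the list alone (median -0.20, adjusted p = 9.24e-05, but adjusted p = 0.19 with an estimated correlation). Examples were adrenomedullin (ADM), -1.11 ± 0.09, and BNIP3, -0.75 ± 0.09. Cholesterol synthesis genes rose in 5 and fell in 2 of 21 (7 and 2 adjusted over the list alone; adjusted p = 0.0848). The unfolded protein and amino acid response had 1 rise and 5 falls in 16 (3 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.0446, but adjusted p = 0.255 with an estimated correlation). One of the falls was DDIT4, -0.58 ± 0.08. Targets of p53 rose in 3 and fell in 1 of 12 (6 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.166). The cell cycle inhibitor CDKN1A changed by 0.57 ± 0.07 and the stress cytokine GDF15 by -2.23 ± 0.11. Immediate early genes rose in 4 and fell in 6 of 19 (5 and 8 adjusted over the list alone; median -0.17, adjusted p = 0.158). They included KLF6, 1.23 ± 0.09, and NR4A2, -1.34 ± 0.11. Antioxidant NRF2 targets fell in 3 of 9, also adjusted over the list alone (median -0.17, adjusted p = 0.0182, but adjusted p = 0.229 with an estimated correlation). TXNRD1 was among them, -0.86 ± 0.08. The metal-binding metallothioneins fell in 2 of 4, also adjusted over the list alone, MT2A by 1.70 ± 0.10 and MT1E by 1.18 ± 0.09.

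Genes of the translation and respiration machinery were called higher one by one with 4T1 cells, but none of their 3 lists passed with an estimated correlation. Ribosomal protein genes rose in 27 of 45 cases and 29 adjusted over the list alone, with 0 falling (median 0.29, adjusted p = 1.98e-11, but adjusted p = 0.193 with an estimated correlation). An example was RPL5, 0.56 ± 0.07. Genes encoded in the mitochondrial genome rose in 8 of 13 (11 rose and 1 fell adjusted over the list alone; median 0.41, adjusted p = 4.79e-05, but adjusted p = 0.268 with an estimated correlation), such as MT-CO2, 0.46 ± 0.08. Nuclear genes of oxidative phosphorylation rose in 6 of 30, also adjusted over the list alone (median 0.18, adjusted p = 0.00145, but adjusted p = 0.193 with an estimated correlation), such as NDUFB2, 0.53 ± 0.11. Mitochondrial ribosomal RNA took 14% to 15.9% of the summed values in these co-cultures and 11% to 13.5% in the untreated monocultures. Changes correlated with GC content across genes (Spearman rho -0.171). Quantile normalization lowered the mitochondrial median to 0.22 and ended its camera call. Correction for GC content and length, added after seeing the data, did so for oxidative phosphorylation, with a median of 0.10.

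Hormone genes and markers of other cell types completed the comparison. Estrogen-responsive genes fell in 5 of 14 cases with 0 rising, also adjusted over the list alone (median -0.13, adjusted p = 0.00145, and 0.0117 with an estimated correlation), among them the carbonic anhydrase CA12, -0.97 ± 0.11. This list also holds CXCL12, counted above among the osteoclast-regulating factors, so these lists overlap. Androgen-responsive genes rose in 3 and fell in 3 of 12, also adjusted over the list alone (median -0.14, adjusted p = 0.954), KLF9 rising by 0.88 ± 0.10. None of ESR1 (-0.14, 95% interval -0.40 to 0.13), ESR2 (-0.27, -0.55 to 0.01) or PGR (-0.20, -0.38 to -0.02, adjusted p = 0.0981) passed, nor did FKBP5 (-0.16, -0.41 to 0.09). Without untreated monoculture replicate 1, PGR passed at -0.31. That fit gave more weight to untreated replicate 2, in which genes of low abundance were raised. Epithelial carcinoma markers, the kind of transcript that 4T1 and TRAMP cells carry, rose in 2 and fell in 2 of 9, also adjusted over the list alone (median -0.09, adjusted p = 0.954). The keratin KRT7 changed by 0.92 ± 0.09 and the protease inhibitor SPINT2 by -0.73 ± 0.11. Chondrocyte markers rose in 1 of 5, also adjusted over the list alone (adjusted p = 0.196; MATN3, 0.82 ± 0.12). Endothelial markers rose in 1 of 6 (1 rose and 3 fell adjusted over the list alone; median -0.16, adjusted p = 0.679; TEK, 0.40 ± 0.10). Adipocyte markers had 0 calls in 3, and of 2 leukocyte markers CD68 fell by 0.85 ± 0.12.

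Matrix genes were higher in co-culture with TRAMP cells too. Levels of these genes in the TRAMP cells themselves were not analysed here either. COL5A3 rose 3.84-fold (1.94 ± 0.14, adjusted p = 4.17e-11, from 4.45 to 6.39), POSTN 2.42-fold (1.28 ± 0.08, adjusted p = 4.63e-12) and COL1A1 2.12-fold (1.08 ± 0.12, adjusted p = 5.87e-07). The largest falls included TFPI2, 2.35-fold lower (-1.23 ± 0.08, adjusted p = 4.63e-12), MMP1, 2.2-fold lower (-1.14 ± 0.09), and MMP3 (-1.01 ± 0.12). In all, 214 genes rose and 158 fell, of which 8 and 7 by at least 2-fold. Groups did not overlap for 3425 genes (23.3%), where chance gives 10%.

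Structural matrix genes rose in 16 of 23 cases with 0 falling (16 and 2 adjusted over the list alone; median 0.46, adjusted p = 1.03e-24, and 0.0025 with an estimated correlation). They included the collagen cross-linking enzyme LOX, 1.01 ± 0.12, VCAN, 1.01 ± 0.08, COL6A3, 0.97 ± 0.08, and COL5A1, 0.91 ± 0.10. Targets of TGF-β rose in 5 and fell in 1 of 14 (6 and 1 adjusted over the list alone; median 0.19, adjusted p = 9.48e-07), TGFBI changing by 0.48 ± 0.07. YAP targets rose in 3 of 10, and 4 adjusted over the list alone (median 0.19, adjusted p = 1.46e-05). They included the receptor kinase AXL, 0.39 ± 0.08, and tissue factor (F3), 0.57 ± 0.11. Of 5 genes in the NOTCH list 2 rose, and 4 adjusted over the list alone (median 0.40, adjusted p = 7.01e-08). The 2 were NOTCH3, 1.09 ± 0.12, and JAG1, 0.82 ± 0.11. HEY1 (0.40 ± 0.11, adjusted p = 0.0516) and HES1 (0.30 ± 0.11, adjusted p = 0.163) did not pass over all genes. Osteoblast markers rose in 5 and fell in 1 of 13, also adjusted over the list alone (median 0.06, adjusted p = 7.67e-05). SPARC rose by 0.76 ± 0.07 and RUNX2 by 0.52 ± 0.09. ALPL differed by 0.01 (95% interval -0.24 to 0.25) and SPP1 by -0.07, and neither passed.

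Inflammatory NF-κB targets fell in 11 of 23 cases and rose in 2 (14 and 2 adjusted over the list alone; median -0.40, adjusted p = 1.03e-09, and 0.0169 with an estimated correlation). Among the falls were CCL20, -0.78 ± 0.10, PTGS2, -0.68 ± 0.09, and IL11, -0.86 ± 0.11. The rises were the adhesion molecule ICAM1, 0.50 ± 0.10, and TNFAIP3, an inhibitor of NF-κB named after its values were seen, 0.49 ± 0.08 with adjusted p = 0.000279. Osteoclast-regulating factors fell in 6 of 11, and 7 adjusted over the list alone (median -0.49, adjusted p = 1.03e-09), including TNFRSF11B, -0.71 ± 0.09. Proteases and inhibitors rose in 1 and fell in 5 of 19 (2 and 6 adjusted over the list alone; median -0.15, adjusted p = 0.00387). NRF2 targets fell in 3 of 9, and 5 adjusted over the list alone (median -0.31, adjusted p = 9.19e-08), for instance TXNRD1, -0.72 ± 0.08, and the quinone reductase NQO1, -0.64 ± 0.12. Only 1 of 23 interferon-stimulated genes passed, IFIT2 at -0.48 ± 0.10, and 4 fell adjusted over the list alone (median -0.11, adjusted p = 0.0259, but adjusted p = 0.525 with an estimated correlation). Cell cycle genes fell in 1 of 25, and 3 adjusted over the list alone (median -0.09, adjusted p = 0.0374, and 0.373 with an estimated correlation). CXCL8 fell by 0.51 ± 0.08, but stood at 0.04 after correction for GC content and length, which was chosen after seeing the data. That correction also removes shifts that follow abundance, and CXCL8 was abundant (13.45 in untreated monoculture). Median changes of the 10 GC bins ran only from 0.03 to -0.05, so GC content is not shown to be what moved CXCL8. That correction gave 584 calls against 372, and changes correlated with GC content across genes (Spearman rho -0.133). Without replicate 2 of the untreated TRAMP co-culture 221 genes passed, array weights gave 926, and a fit of these 6 libraries alone gave 602.

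**Figure D2:**
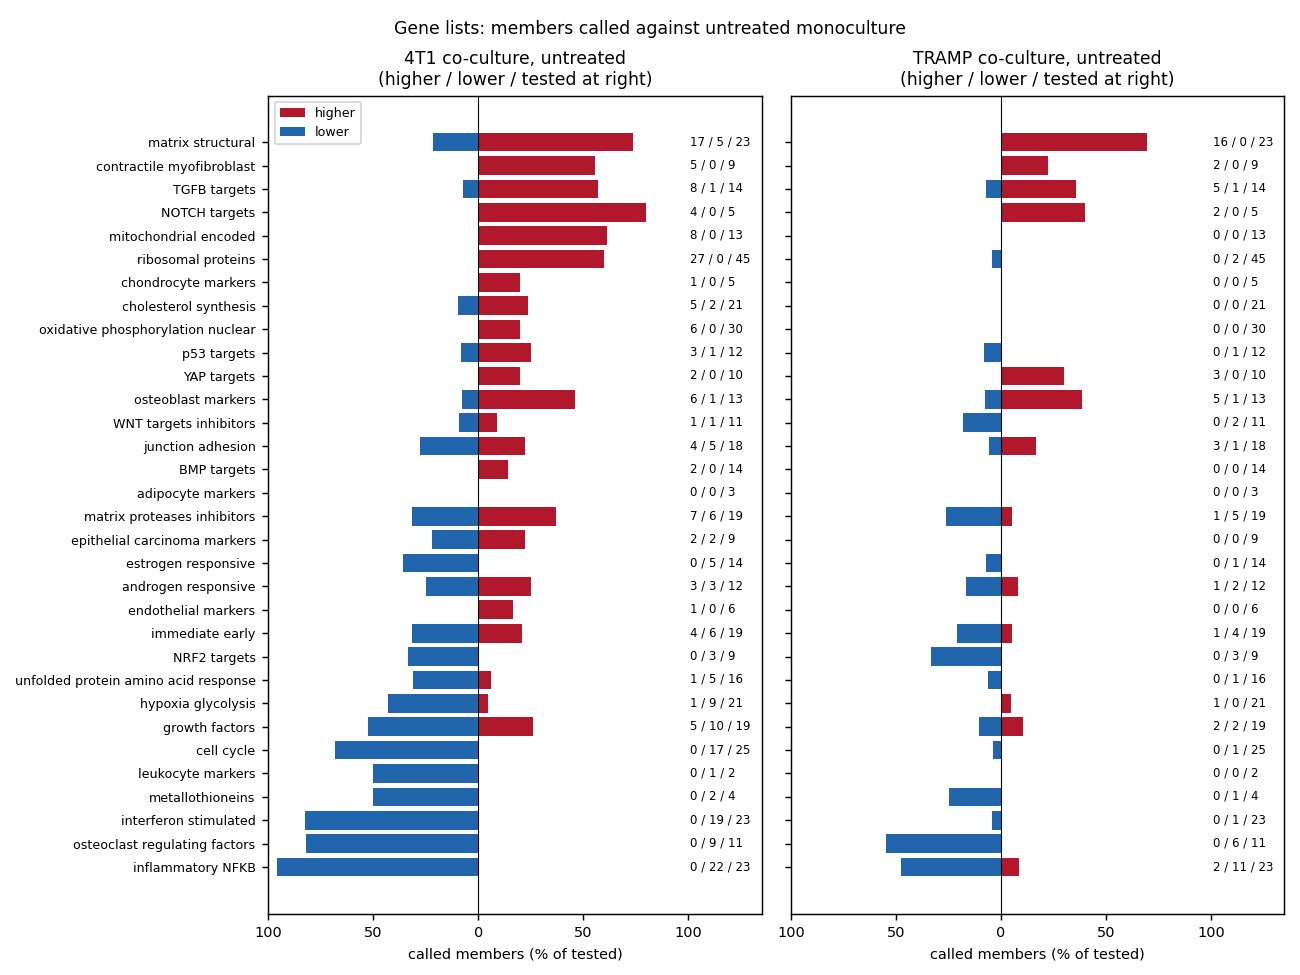
Percentage of tested members called higher (red, to the right) or lower (blue, to the left) in untreated co-culture with 4T1 (left panel) or TRAMP cells (right panel) against untreated monoculture, for 32 gene lists on the y axis, with the numbers higher, lower and tested at the right. NF-κB targets fell in 22 of 23 cases with 4T1 and 11 of 23 with TRAMP cells, and structural matrix genes rose in 17 and 16 of 23.

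Set directly against each other, untreated co-cultures with 4T1 cells had less inflammatory transcript than those with TRAMP cells, and single matrix genes differed in both directions. POSTN was higher by 2.14 ± 0.08 (11.11 against 8.97, adjusted p = 2.74e-19), COL5A3 by 2.27 ± 0.14 and CTGF by 2.02 ± 0.10. CXCL8 was lower by a log2 difference of -3.30 ± 0.08 (9.63 against 12.93, adjusted p = 3.63e-25), CXCL1 by -3.45 ± 0.11 and IL6 by -2.79 ± 0.11. With 4T1 cells 1374 genes were higher and 1468 lower, 69 and 89 of them by at least 2-fold, and groups did not overlap for 5018 genes (34.1%, chance 10%). NF-κB targets were lower in 21 of 23 cases, also adjusted over the list alone (median -1.66, adjusted p = 1.83e-58). Interferon-stimulated genes were lower in 18 of 23 and 20 adjusted over the list alone (median -0.58, adjusted p = 5.39e-18), CXCL10 differing by -1.35 ± 0.11 and OAS3 by -1.14 ± 0.08. Cell cycle genes were lower in 13 of 25 and 16 adjusted over the list alone (median -0.25, adjusted p = 1.67e-07). Contractile genes were higher in 5 of 9 and 6 adjusted over the list alone (adjusted p = 5.67e-07). Structural matrix genes were higher in 11 and lower in 5 of 23 (12 and 5 adjusted over the list alone; adjusted p = 2.51e-05, but adjusted p = 0.131 with an estimated correlation). Ribosomal protein genes were higher in 39 of 45 and 41 adjusted over the list alone (median 0.41, adjusted p = 1.19e-23, but adjusted p = 0.0519 with an estimated correlation). Mitochondrial ribosomal RNA took 14% to 15.9% of values with 4T1 and 10.3% to 11.6% with TRAMP cells. RUNX2 differed by 0.03 (95% interval -0.16 to 0.22).

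The effects of the 2 kinds of cancer cell were set side by side. Of the 372 genes called with TRAMP cells, 343 (92.2%) had the same sign with 4T1 cells, and 163 were called higher and 118 lower in both, where independent lists would share 23.1 and 17.9. Both comparisons use the untreated monocultures. In 100 simulations of unchanged groups against those controls, the 372 genes with the strongest TRAMP difference had on average 93.2% of the same sign. This check was added after seeing the data. The simulations held no 4T1 effect, whereas 3251 genes were called with 4T1 cells. Their share and correlation therefore cannot say what the shared controls alone give in these data. Across genes the correlation was 0.522, within the simulated values (mean 0.501, highest 0.526), and the covariance was 0.0298 against a simulated mean of 0.0059 (highest 0.00632), a difference of 0.0239; part of the overlap may come from the shared controls. The hormone-treated groups share no library: there, 226 genes were called higher and 225 lower in both (independent lists, 41.2 and 37.9), 3 and 10 went opposite ways, and the correlation across genes was 0.493, with genes not being independent replicates. The slope of the TRAMP on the 4T1 effect, over the genes called with 4T1 cells, was 0.248. Of the 671 genes called with TRAMP cells there, 87.5% had the same sign with 4T1 cells. Across treatments, which also share no library, the correlation was 0.342 for untreated 4T1 against R1881-treated TRAMP co-culture. There 73.2% had the same sign, 170 genes were called higher and 166 lower in both (independent lists, 39.5 and 34.5), and 19 and 33 went opposite ways. For E2-treated 4T1 against untreated TRAMP co-culture the correlation was 0.441, with 91.1% of the same sign, 173 higher and 123 lower in both (24.1 and 19.6), and 0 and 7 opposite. Both partners are mouse cells, so mouse reads counted as human could raise the same genes in both co-cultures. Comparisons without a shared library do not remove this, and it was not tested with TRAMP cells.

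**Figure D3:**
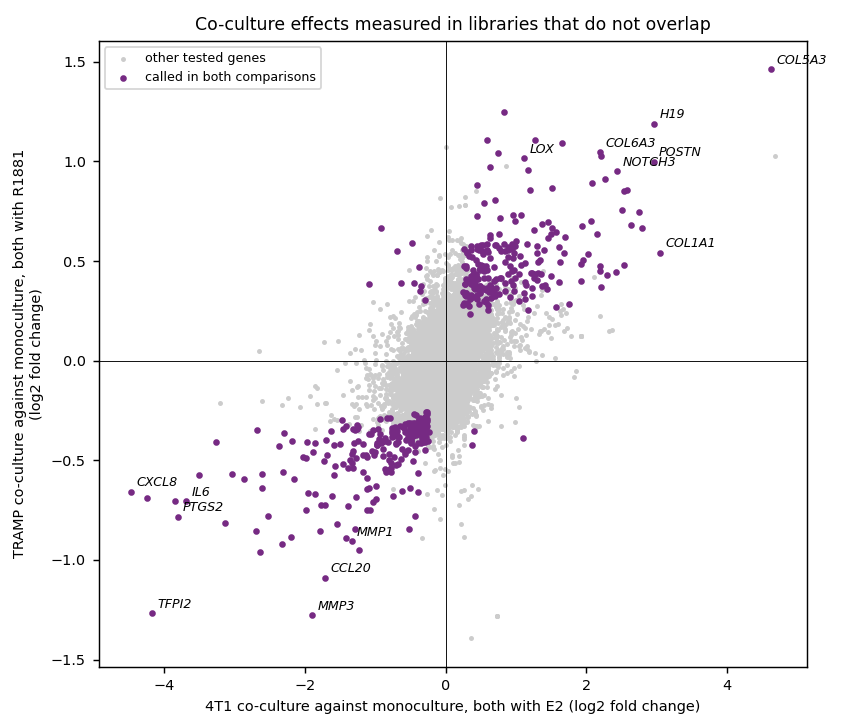
Log2 change of each tested gene with 4T1 cells under E2 (x axis) against its change with TRAMP cells under R1881 (y axis), each against monoculture with the same steroid; each point is a gene, and purple points were called in both. The correlation across genes is 0.493, with 226 genes called higher and 225 lower in both.

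Interferon-stimulated genes were higher as a set in E2-treated than in untreated monoculture, with 2 single calls, and estrogen-responsive genes had no call. The interferon set also had a median of 0.18 with R1881 against the same untreated libraries, and its difference between the steroids had adjusted p = 0.256 with an estimated correlation. The chemokine CXCL10 (chromosome 4, 76021117 to 76023497, minus strand) rose 1.69-fold, from 6.04 ± 0.26 to 6.79 ± 0.17 (SD, n = 3), a change of 0.75 ± 0.11 with adjusted p = 0.00183. The antiviral gene IFIT1 (chromosome 10, 89392546 to 89406486, plus strand) rose 1.59-fold, from 8.20 ± 0.22 to 8.87 ± 0.19, a change of 0.67 ± 0.11 with adjusted p = 0.0121. These were the only 2 calls among 14704 genes, with 921 at an unadjusted p under 0.05 and 1388 without overlap (9.44%, chance 10%). The interferon list had 2 rises in 23, and 15 adjusted over the list alone (median 0.34, adjusted p = 2.08e-30, and 0.0156 with an estimated correlation). IFIT3, 0.46 ± 0.09, and IFIH1, 0.46 ± 0.09, did not pass over all genes. NF-κB targets had 0 calls, and 9 rises adjusted over the list alone (median 0.20, adjusted p = 6.02e-13, and 0.0224 with an estimated correlation). Estrogen-responsive genes had 0 calls in 14 by either adjustment (median 0.02, adjusted p = 0.636). ESR1 differed by -0.11 (95% interval -0.38 to 0.15), PGR by -0.13 (-0.31 to 0.05) and COL1A1 by 0.12 (-0.13 to 0.37), none passing. Changes fell with GC content across genes (Spearman rho -0.4). The calls numbered 0 without untreated replicate 3 or E2 replicate 3, 5 without untreated replicate 1 and 36 without E2 replicate 1. Array weights gave 20 and a filter at a linear value of 50 gave 11, and a constant prior variance ended the IFIT1 call.

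R1881 in monoculture gave no call. CXCL10 stood at 6.63 against 6.04 in untreated cells, a difference of 0.59 ± 0.11 with adjusted p = 0.062. The cementum protein gene CEMP1 differed by -0.60 ± 0.11 with adjusted p = 0.0508. By limma 0 genes passed over all genes, with 1749 at an unadjusted p under 0.05 and 3267 without overlap (22.2%, chance 10%). Interferon-stimulated genes had 11 rises adjusted over the list alone (median 0.18, adjusted p = 2.31e-08, but adjusted p = 0.317 with an estimated correlation). NF-κB targets also had 11 (median 0.13, adjusted p = 1.21e-05, but adjusted p = 0.317 with an estimated correlation). Androgen-responsive genes had 0 calls in 12 by either adjustment (median -0.04, adjusted p = 0.969). FKBP5 differed by -0.05 (95% interval -0.31 to 0.20). Changes fell with GC content (Spearman rho -0.588 across genes), the strongest such relation of the comparisons made. Array weights gave 464 calls, a fit of these 6 libraries alone 125, a filter at 50, median centring and protein-coding genes alone 2 each, and a constant prior variance or leaving out R1881 replicate 3 gave 1.

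E2 and R1881, both steroids and here at the same dose and time, were compared directly in monoculture, a comparison added after seeing the data. By limma 0 genes differed, with 549 at an unadjusted p under 0.05, and 1386 without overlap (9.43%, chance 10%). There was 1 call with array weights, with the stricter filter and with these 6 libraries alone, and 4 without R1881 replicate 2. The intervals of the difference, E2 minus R1881, ran from -0.34 to 0.19 for ESR1, -0.30 to 0.21 for FKBP5 and 0.05 to 0.55 for COL1A1, each with adjusted p of 1.0, so effects of those sizes were not excluded. Interferon-stimulated genes had a median difference of 0.11, with 2 higher under E2 adjusted over the list alone (adjusted p = 1.14e-07, but adjusted p = 0.256 with an estimated correlation).

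In 4T1 co-culture 842 genes differed by small amounts between E2-treated and untreated libraries, and 142 of them kept their call after a correction for GC content and length. XYLT1, which starts the sugar chains of proteoglycans (chromosome 16, 17101769 to 17470881, minus strand), rose 1.63-fold, from 5.91 ± 0.11 to 6.61 ± 0.09 (SD, n = 3), a change of 0.70 ± 0.10 with adjusted p = 0.000415. Fibronectin (FN1) rose by 0.47 ± 0.08 and COL1A2 by 0.40 ± 0.08, whereas the receptor gene ROR1 fell by 0.61 ± 0.11 and SPP1 by 0.51 ± 0.12. In all, 428 genes rose and 414 fell, 1 of them by at least 2-fold, and groups did not overlap for 2693 genes (18.3%, chance 10%). Structural matrix genes rose in 9 and fell in 2 of 23 (12 and 2 adjusted over the list alone; median 0.23, adjusted p = 7.24e-06, but adjusted p = 0.282 with an estimated correlation), including COL1A1, 0.57 ± 0.12. Ribosomal protein genes fell in 21 of 45, and 38 adjusted over the list alone (median -0.27, adjusted p = 4.8e-25, but adjusted p = 0.247 with an estimated correlation), such as RPL38, -0.56 ± 0.10. Mitochondrially encoded genes fell in 1 of 13, and 9 adjusted over the list alone (median -0.26, adjusted p = 6.38e-05, but adjusted p = 0.56 with an estimated correlation). Estrogen-responsive genes rose in 1 of 14, also adjusted over the list alone (median 0.07, adjusted p = 0.461). This was the lysosomal protease CTSD, 0.36 ± 0.10, whose call was lost with array weights, a constant prior or without any 1 of 5 libraries. ESR1 differed by 0.09 (95% interval -0.18 to 0.35) and PGR by 0.16 (-0.02 to 0.34).

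Changes with E2 in 4T1 co-culture rose with GC content (Spearman rho 0.373 across genes), while mitochondrial ribosomal RNA took 11.1% to 12.4% of values with E2 and 14% to 15.9% without. After correction for GC content and length, chosen after seeing the data, 221 genes were called, 142 of them shared with the 842. XYLT1, FN1, COL1A2, ROR1, SPP1 and RPL38 kept their calls, as did the matrix protease MMP9 (0.66 ± 0.13) and the retinoic acid receptor gene RARG (0.60 ± 0.11). COL1A1 (0.23), NOTCH3 (0.16) and MT-CO2 (-0.03) no longer passed, and CXCL8, which had fallen by 0.41 ± 0.08, stood at 0.19. The mitochondrial list turned to a median of 0.18, and the NF-κB list went from 0.01 to 0.17. Calls numbered 344 without untreated replicate 2, 450 without untreated replicate 3, 525 without E2 replicate 1, 288 with array weights and 59 in a fit of these 6 libraries alone. In that fit MMP9, RARG, ROR1 and SPP1 did not pass, and SPP1 also lost its call with array weights and without untreated replicate 2 or E2 replicate 3.

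**Figure D4:**
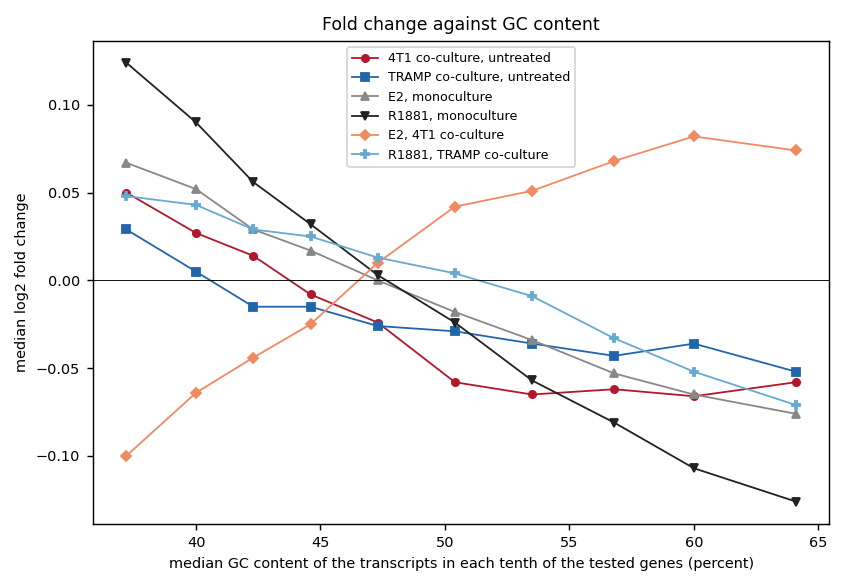
Median log2 change (y axis) of the tested genes in 10 equal bins of transcript GC content (x axis, median GC in %), one line per comparison. With R1881 in monoculture the median runs from 0.12 in the lowest bin (37.2% GC) to -0.13 in the highest (64.1%), and with E2 in 4T1 co-culture from -0.10 to 0.07.

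COL1A1 was lower in R1881-treated than in untreated TRAMP co-culture, at 9.96 ± 0.30 against 10.68 ± 0.23 (SD, n = 3), a 1.65-fold difference (-0.72 ± 0.12, adjusted p = 0.0279). It was the only call by limma, with 900 genes at an unadjusted p under 0.05 and 2077 without overlap (14.1%, chance 10%). COL5A3 (-0.67 ± 0.14), the actin gene ACTB (-0.48 ± 0.10) and COL5A1 (-0.47 ± 0.10) did not pass. Structural matrix genes fell in 1 of 23, and 7 adjusted over the list alone (median -0.09, adjusted p = 1.28e-07, but adjusted p = 0.128 with an estimated correlation). Mitochondrially encoded genes fell in 0 of 13, and 9 adjusted over the list alone (median -0.23, adjusted p = 2.43e-13, but adjusted p = 0.128 with an estimated correlation). Mitochondrial ribosomal RNA took 9.44% to 10.9% of values with R1881 and 10.3% to 11.6% without. Androgen-responsive genes had 0 calls in 12 (median 0.06, adjusted p = 0.169), and FKBP5 differed by 0.06 (95% interval -0.19 to 0.31). Changes fell with GC content (Spearman rho -0.363 across genes). The COL1A1 call was lost with the looser filter, with a constant prior and without untreated replicate 1 or 2 or R1881 replicate 1 or 3. The number of calls was 162 with array weights, 24 in these 6 libraries alone, 8 with a replicate block, 5 with the stricter filter or without the 2 libraries with raised low-abundance genes, 3 without untreated replicate 3 and 11 without R1881 replicate 2.

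With E2 in both cultures, matrix genes were again higher and inflammatory and interferon genes lower with 4T1 cells. COL5A3 rose by 4.62 ± 0.14 (adjusted p = 1.37e-22) and COL1A1 by 3.05 ± 0.12, while CXCL8 fell by 4.47 ± 0.08 (adjusted p = 3.81e-29) and IL6 had the change -3.69 ± 0.11. In all, 1657 genes rose and 1827 fell, 150 and 162 by at least 2-fold, and groups did not overlap for 4503 genes (30.6%, chance 10%). Interferon-stimulated genes fell in 22 of 23, and 23 adjusted over the list alone (median -1.17, adjusted p = 1.18e-31, and 0.00274 with an estimated correlation). IFIT1, named after its values were seen, fell by 1.27 ± 0.11. NF-κB targets fell in 22 of 23, also adjusted over the list alone (median -2.52, adjusted p = 1.56e-53), and cell cycle genes in 19 of 25, and 21 adjusted over the list alone (adjusted p = 8.79e-13). Structural matrix genes rose in 17 and fell in 4 of 23, also adjusted over the list alone (median 1.06, adjusted p = 3.8e-14). Ribosomal protein genes rose in 5 and fell in 4 of 45, also adjusted over the list alone (median 0.03, adjusted p = 0.718), and mitochondrially encoded genes in 0 of 13; changes rose with GC content (Spearman rho 0.259 across genes). Of the calls, 784 higher and 971 lower were shared with the untreated comparison (independent lists, 179 and 207). The correlation across genes was 0.779.

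With R1881 in both cultures, COL5A3 was higher with TRAMP cells by 1.46 ± 0.14, COL6A3 by 1.05 ± 0.08 and LOX by 1.02 ± 0.12. Lower were MMP3 (-1.28 ± 0.12), TFPI2 (-1.27 ± 0.08, adjusted p = 4.08e-12) and CCL20 (-1.09 ± 0.10). In all, 366 genes rose and 305 fell, 11 and 7 by at least 2-fold, and groups did not overlap for 4136 genes (28.1%, chance 10%). Hypoxia and glycolysis genes rose in 7 of 21 (10 rose and 1 fell adjusted over the list alone; median 0.20, adjusted p = 1.36e-08, and 0.0423 with an estimated correlation). Among them were the glucose transporter SLC2A1, 0.61 ± 0.09, NDRG1, 0.82 ± 0.12, and hexokinase HK2, 0.66 ± 0.12. Mitochondrially encoded genes fell in 12 of 13, also adjusted over the list alone (median -0.54, adjusted p = 6.86e-19, and 0.0303 with an estimated correlation), MT-CO2 changing by -0.58 ± 0.08. Mitochondrial ribosomal RNA took 9.44% to 10.9% of values in co-culture and 10.4% to 11.8% in monoculture. NF-κB targets rose in 2 and fell in 13 of 23 (2 and 14 adjusted over the list alone; median -0.57, adjusted p = 1.14e-15). Interferon-stimulated genes fell in 9, and 13 adjusted over the list alone (median -0.23, adjusted p = 3.81e-12), IFIT2 changing by -0.82 ± 0.10. NRF2 targets fell in 4 of 9, and 6 adjusted over the list alone (median -0.32), NQO1 changing by -0.78 ± 0.12. Shared with the untreated comparison were 141 higher and 91 lower genes (independent lists, 5.33 and 3.28), with a correlation across genes of 0.617. Calls numbered 351 without co-culture replicate 1, 421 without co-culture replicate 3, 348 without monoculture replicate 2, 340 without monoculture replicate 3, 1742 with array weights and 1520 in these 6 libraries alone.

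The effect of E2 differed between 4T1 co-culture and monoculture for 397 genes by the interaction test, 152 in the higher and 245 in the lower direction (205 and 132 with quantile normalization). IFIT1 rose from 8.20 to 8.87 in monoculture and stood at 7.85 and 7.60 in co-culture, a difference of effects of -0.92 ± 0.16 with adjusted p = 0.00675. Interferon-stimulated genes were called lower in 11 of 23 cases, and 13 adjusted over the list alone (median -0.44, adjusted p = 1.7e-14, but adjusted p = 0.242 with an estimated correlation). XYLT1 had the difference 0.95 ± 0.14 (adjusted p = 0.000941). These differences rose with GC content (Spearman rho 0.478 across genes), and after correction for GC content and length, chosen after seeing the data, 9 genes were called, 8 of them among the 397. The number of calls was 1000 without E2 monoculture replicate 1, 9 without its replicate 3, 167 without its replicate 2, 117 and 61 without untreated monoculture replicates 2 and 3, 126 and 188 without untreated co-culture replicates 2 and 3, and 229 without E2 co-culture replicate 1. It was 238 without the 2 libraries with raised low-abundance genes, 680 with the stricter filter and 253 with the looser one. A constant prior gave 150 and these 12 libraries alone gave 9.

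For R1881, the interaction test between TRAMP co-culture and monoculture called 0 genes by limma, with 551 at an unadjusted p under 0.05 and 1 call without untreated co-culture replicate 2. The COL1A1 difference of effects was -0.54 (95% interval -0.90 to -0.18, adjusted p = 0.999). Mitochondrially encoded genes had 7 in the lower direction adjusted over the list alone (median -0.36, adjusted p = 1.08e-18, but adjusted p = 0.109 with an estimated correlation).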

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

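The tests of GC content, of mouse reads and of low values in the untreated libraries were chosen only after the results were seen, whereas leaving out 1 library and regrouping the samples were chosen before their results were seen. The genes listed under 4T1 against TRAMP co-culture, and under the effect of E2 in 4T1 co-culture against its effect in monoculture, were picked out because a test of the difference itself was passed. The patterns of 4T1 cells against monoculture and of interferon-stimulated genes come from other comparisons and were chosen for follow-up.

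Between the untreated co-cultures 2842 genes differed. Higher with 4T1 than with TRAMP cells were COL5A3 (2.27), POSTN (2.14), TAGLN (2.14), PRRX1 (2.08), CTGF (2.02), NREP (1.999), COL1A1 (1.52) and SPARC (1.55). Smaller log2 differences in this direction were found for NQO1 (0.56), SPP1 (0.67), RPL5 (0.52), NDUFB2 (0.64) and MT-CO2 (0.67). Lower with 4T1 cells were CXCL1 (-3.45), CXCL8 (-3.30), PTGS2 (-3.06), CXCL6 (-3.03), CSF3 (-2.94), IL6 (-2.79), TNC (-2.01), FGF2 (-1.66), ICAM1 (-1.48), CXCL10 (-1.36), TNFRSF11B (-1.33), OAS3 (-1.14), ADM (-0.92), VEGFA (-0.86) and F3 (-0.72).

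The first pattern is the response to 4T1 cells, 3251 genes against untreated monoculture. After correction for GC content and transcript length 89.6% of these genes kept their call in the same direction, which argues against that trend as the whole cause. Mouse reads counted as human could raise genes but not lower them beyond a shift of all genes, and 131 called genes were at least 2-fold lower. For the genes that rose this stays open: 9 epithelial carcinoma markers had a median change of -0.088, but 2 rose and 2 fell, and levels in 4T1 cells were not analysed here. A response of the osteoblasts to 4T1 cells, which the design names, remains a hypothesis beside that.

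The effect of E2 differed between 4T1 co-culture and monoculture for 397 genes. Differences of effects, in log2, were higher in co-culture for XYLT1 (0.95), PLEC (0.78), FASN (0.78), MEG3 (0.73), IGF2 (0.73), BGN (0.70) and COL6A1 (0.62). They were lower for IFIT1 (-0.92), RPL38 (-0.76), LUM (-0.74), IFIT2 (-0.72), CXCL8 (-0.65, but 0.13 after the GC and length correction) and CXCL1 (-0.59). Values of the other genes are given before that correction only. After it 8 of the 397 genes kept their call, so the genes listed here are not shown to hold.

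The second pattern is this difference, together with the 842 genes called for E2 within 4T1 co-culture; an action of E2 that depends on the cancer cells, which the design names, stays open. Of the 397 genes 2.02% kept their call after the GC and length correction. The others went from a median size of 0.54 to 0.28 while their median SE went from 0.135 to 0.117. Those calls thus ended because the differences shrank. A GC trend between libraries could give this. The correction also removes shifts that follow abundance, so GC content, length and abundance cannot be told apart here. Likewise 700 of the 842 genes lost their call, with a median size of 0.366 before and 0.196 after and a median SE of 0.0975 before and 0.0842 after. The other 142 kept their call, which argues against the trend as the cause of all 842, though not for any single gene. Regrouping treatment labels within each culture gave as many genes as the real 397 in 3 of 100 splits, the real one included, a share under 0.05. The others among the 3 called 1024 and 468, more than the real split. The other splits left out only the real grouping of both cultures together. Some could keep or reverse the real grouping in 1 culture and so hold part of a treatment difference. These counts therefore cannot say what regrouping free of treatment gives. Whether a structure of the samples other than treatment is present was not tested.

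The third pattern is the higher level of interferon-stimulated genes in E2-treated monoculture, a median of 0.34 over 23 genes. After the GC and length correction the median was 0.27 (0.265), with adjusted p = 0.0101 with an estimated correlation, which argues against that trend as the whole cause. Leaving out any 1 of the 6 libraries left a median of at least 0.257, the lowest being without untreated replicate 3, which argues against 1 library as the whole cause. Untreated libraries that happened to be low in these genes could give the same picture: the median with R1881 against the same libraries was 0.18 (0.182), and the difference of the steroids, 0.11, had adjusted p = 0.256 with an estimated correlation. An effect of E2 and a low set of untreated libraries cannot be told apart, because both comparisons rest on the same 3 libraries. In 4T1 co-culture, which has other untreated libraries, the mean of these genes did not rise with E2. It lay at 7.58 to 7.70 with E2 and 7.65 to 7.82 without. That culture also holds cancer cells, so this does not decide between the explanations.

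For the counts of called genes between 2 groups, other splits of the 6 libraries were too few, at 10, for a share under 0.05. As many genes as in the real split were called in 1 of 10 for 4T1 co-culture (3251, highest other 0), TRAMP co-culture (372, highest other 0), 4T1 against TRAMP (2842, highest other 1), E2 in 4T1 co-culture (842, highest other 3), R1881 in TRAMP co-culture (1, highest other 0), 4T1 under E2 (3484, highest other 0) and TRAMP under R1881 (671, highest other 0). For E2 in monoculture it was 2 of 10 (2, highest other 3), for R1881 in monoculture 10 of 10 (0 by limma with 1749 at an unadjusted p under 0.05, highest other 1) and for E2 against R1881 10 of 10 (0 by limma with 549 at an unadjusted p under 0.05, highest other 0). For the difference of the R1881 effect, 0 genes by limma in the real split with 551 at an unadjusted p under 0.05, it was 100 of 100, with 71 in the highest other. Where the real split called 0 genes every split called as many by construction, so these 3 counts say nothing about chance.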

How the results depend on the processing

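The GC and length correction, the omission of the 2 libraries with raised low-abundance genes, the restriction to protein-coding genes and the comparison of E2 with R1881 were chosen only after the data were seen. Over all alternatives and omitted libraries, values of named genes kept direction and side of the threshold in 4731 cases, lost their call in 157, gained one in 64 and reversed in 4; for gene lists these numbers were 479, 41, 6 and 2. The reversals all came with the GC and length correction: CXCL8 with TRAMP cells (0.035), with E2 in 4T1 co-culture (0.19) and in the difference of E2 effects (0.13), RPS6 with E2 in 4T1 co-culture (0.025), and in that comparison the mitochondrially encoded list (0.18) and the NF-κB list, whose median kept its sign (0.01 before, 0.17 after) while its camera direction turned from lower to higher. Because the correction also removes shifts that follow abundance, these reversals are not shown to come from GC content or length. It also gave 584 genes with TRAMP cells, 221 with E2 and 3 with R1881 in co-culture, and 9 for the difference of E2 effects. Asking for a fold change of at least 2 left 256 genes with 4T1 cells, 15 with TRAMP cells, 158 between them, 0 with E2 in monoculture, 1 with E2 in 4T1 co-culture, 0 with R1881 in TRAMP co-culture, 312 with 4T1 cells under E2, 18 with TRAMP cells under R1881 and 1 for the difference of E2 effects, by its construction. Array weights gave 926 with TRAMP cells, 20 with E2 and 464 with R1881 in monoculture, 288 with E2 and 162 with R1881 in co-culture, 1742 with TRAMP cells under R1881 and 1 for E2 against R1881. Fitting the compared libraries alone gave, in the same order, 602, 5, 125, 59, 24, 1520 and 1, and 9 for the difference of E2 effects. The filter at 50, which tested 7386 genes, gave 11 with E2 and 2 with R1881 in monoculture. It gave 5 with R1881 in TRAMP co-culture, 680 for the difference of E2 effects and 1 for E2 against R1881. The looser filter (17251 genes with any log2 value above 0) gave 0 for R1881 in TRAMP co-culture and 253 for the difference of E2 effects. A constant prior variance gave 1, 1, 0 and 150 for E2 and R1881 in monoculture, R1881 in TRAMP co-culture and the difference of E2 effects. Median centring gave 4 and 2, and 13529 protein-coding genes 7 and 2, for E2 and R1881 in monoculture. Quantile normalization gave 3 for R1881 in TRAMP co-culture and turned the difference of E2 effects from 152 higher and 245 lower to 205 higher and 132 lower. Leaving out the 2 libraries gave 5 for R1881 in TRAMP co-culture and 238 for the difference of E2 effects. The replicate block gave 8 for R1881 in TRAMP co-culture, where COL5A3, ACTB and COL5A1 passed with it, and moved no other count by over 1.5 times. Same-numbered libraries showed no strong pairing. Pairs of them had correlations of deviations from -0.21 to 0.24, and 0 comparisons had every pair over 0.1. Between untreated TRAMP co-culture and monoculture, however, 3 of 3 libraries were closest to their own number (0.049 to 0.1). Between R1881-treated and untreated TRAMP co-culture 2 of 3 were (0.048 to 0.24). A weak pairing there is not excluded. Leaving out 1 library gave, by limma as throughout, 2054 to 2723 genes for 4T1 against TRAMP, 2560 to 3033 with 4T1 cells, 2635 to 3449 under E2, 221 to 434 with TRAMP cells (lowest without untreated co-culture replicate 2) and 340 to 567 under R1881 (340 and 348 without R1881 monoculture replicates 3 and 2, 351 and 421 without co-culture replicates 1 and 3). For E2 it gave 0 to 36 in monoculture (0 without untreated or E2 replicate 3, 5 without untreated replicate 1, 36 without E2 replicate 1) and 344 to 950 in 4T1 co-culture (344 and 450 without untreated replicates 2 and 3, 525 without E2 replicate 1). For R1881 it gave 0 to 1 in monoculture (1 without R1881 replicate 3) and 0 to 11 in TRAMP co-culture (0 without untreated replicate 1 or R1881 replicate 1 or 3, 3 without untreated replicate 3, 11 without R1881 replicate 2), and for E2 against R1881 0 to 4 (4 without R1881 replicate 2). The difference of E2 effects ran from 9 to 1000: 1000, 167 and 9 without E2 monoculture replicates 1, 2 and 3, 117 and 61 without untreated monoculture replicates 2 and 3, 126 and 188 without untreated 4T1 co-culture replicates 2 and 3, and 229 without E2-treated 4T1 co-culture replicate 1. The difference of R1881 effects ran from 0 to 1 (1 without untreated TRAMP co-culture replicate 2). Apart from fewer genes or libraries in a fit, the cause was not tested. Pseudocounts of other sizes were not run because the values were on a log scale already, and edgeR and DESeq2 were not run because no counts were used. Scaling moved the median of all genes by at most 0.036, and the filter at 50 by 0.073. Library depth is unknown, so no limit from depth was computed.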

Other observations

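Co-culture also moved other genes, taken from the largest changes of each comparison. With 4T1 cells the hedgehog-binding protein gene HHIP rose by 2.76 ± 0.10, the imprinted noncoding RNA H19 by 2.67 ± 0.14, NREP 5.66-fold and the VEGF receptor gene FLT1 by 2.46 ± 0.12, each a log2 change ± SE unless given as a fold, against untreated monoculture (limma, n = 3 libraries per group). The arginine transporter gene SLC7A2 changed by -2.99 ± 0.09 and the complement factor gene CFB by -2.95 ± 0.08. H19 was also higher under E2 with 4T1 cells, 2.96 ± 0.14, and under R1881 with TRAMP cells, 1.19 ± 0.14, where the nuclear noncoding RNA NEAT1 rose by 1.25 ± 0.14. Under E2 with 4T1 cells the matrix proteoglycan biglycan (BGN) rose by 2.79 ± 0.11.

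With TRAMP cells the mesenchymal transcription factor gene SNAI2 rose by 1.01 ± 0.12, the protease-activated receptor gene F2RL1 by 1.01 ± 0.11 and the membrane adaptor gene PAG1 by 0.95 ± 0.10. The protease inhibitor genes SERPINB2 and SERPINE2 changed by -0.83 ± 0.11 and -0.78 ± 0.07. The groups did not overlap for any gene named in this part, and the largest adjusted p was 3.06e-06, for SERPINB2.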
